A study of Mus musculus with 6 samples.

How the data were processed

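RNA was profiled in 6 samples of lineage-negative hematopoietic cells from C57BL/6 mice, 3 untreated and 3 treated with Pam3CSK4. Libraries were made from RNA of whole cell lysates with a stranded mRNA kit, per the labels' protocols. Each deposited file holds whole-number counts per gene entry for 1 library, and the authors' values were not normalised, since totals differ between libraries. Reads were processed with cutadapt, Trimmomatic, STAR and featureCounts against mouse genome build mm10, per the submitters' processing notes, which give no versions. The annotation release and the strand and multi-mapping settings of the counting are not given in the sources used here. The near-identical processed copies Rps12-ps11 to Rps12-ps16 had counts that differed by a factor of at most 1.01 within a library, as if reads that match several loci were counted at each. Other near-identical copies were not tested for shared reads, and their counts are uncertain. These include Hba-a1 and Hba-a2, the Oas1, Ifit3, Serpina3, Bcl2a1 and Cd209 copies and immunoglobulin segments. Between 19.8% and 29.6% of the counts of a library fell on unnamed gene models and 0.728% to 2.87% on mitochondrial genes.

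Groups were taken from the labels. All columns were mapped to a sample. Library totals ran from 68559818 to 79064687 counts, so that 3 counts, used as the floor for a library without counts, stood for 0.0379 to 0.0438 CPM. Intervals and floors cover counting error only. Counts were scaled by TMM (factors 0.575 in Pam3CSK4 replicate 1, 0.979 in untreated replicate 3 and 1.13 to 1.17 in the others) and filtered with edgeR's filterByExpr, which left 21057 of 54057 entries. Gene symbols were matched to GENCODE release M21 on GRCm38, the same assembly as mm10, for coordinates, exon overlaps, transcript length and GC content. Of the tested entries 69.1% had a symbol in that release, and of the changed genes 87.7%. Trends with length and GC content used 8602 tested protein-coding genes with a mean log2 CPM above 3.

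Treated and untreated groups were compared with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit, group as the only term, two-sided, Benjamini-Hochberg adjusted p under 0.05), as fixed before the data were examined together with the gene lists, the rule for named genes and the other normalisations, filters and tests described below. Log2 changes are Pam3CSK4 over untreated, and CPM values are TMM-normalised. The standard errors (SE) of log2 changes are the absolute change divided by the square root of the F statistic of the test. They are therefore approximate. Lists were tested with camera in limma 3.58.1 against all other tested genes, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one, adjusted over 25 lists. They held 573 genes, of which 552 were tested, and covered TLR2 receptor and adaptors, NF-κB response, cytokines and chemokines, interferon-stimulated genes, MHC class I presentation, monocyte and macrophage markers, dendritic cell and MHC class II genes, primary granules, neutrophil maturation, myeloid transcription factors, stem and progenitor markers, erythroid, megakaryocyte, mast cell, B lymphoid, T and NK lymphoid, stromal and endothelial genes, mTOR and TBK1 pathway components, cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, microbicidal genes, and p53 targets with heat shock genes.

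The genes named are those of the pathway in the series title with direct partners, and the 10 largest changes in each direction. The latter had to pass the threshold with a mean of at least 5 CPM in the higher group, a symbol that is no predicted model or pseudogene and no overlap between treated and untreated values. For each list up to 4 members with the largest changes that passed at a mean of at least 1 CPM were added, with any needed to describe a list that went both ways. Genes with all libraries of a group at 0 are given as at least so many-fold apart, from 3 counts per library.

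The fit was tested on simulated counts with 100 genes changed by each of 2 sizes. With the spread of all 6 libraries it recovered 0% of genes changed by 1 on the log2 scale and 20% of those changed by 3, with 1 of the unchanged genes called. With the spread of the 4 close libraries it recovered 100% of both, with 7 unchanged genes called. The first simulation used a spread for each gene and the second 1 common spread. Both drew 3 libraries per group with independent noise. They therefore reproduce neither the smaller groups of the 4 close libraries nor a deviation shared by 2 libraries, and their contrast does not measure the real analyses. The other analyses fixed then were DESeq2 size factors and total counts in place of TMM, no filter and a stricter filter (at least 5 CPM in 3 libraries), DESeq2 1.42.0 on all entries with counts, limma-voom, the replicate number as a block, and each library left out in turn. Further alternatives were chosen after seeing the data, namely the 4 close libraries alone, a term for the 2 divergent libraries, the length trend of each library as a covariate, and protein-coding genes alone, without and with offsets for length and GC content from mgcv 1.9.3.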

Results

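The data were poly(A) RNA profiles of cultured mouse hematopoietic stem and progenitor cells, the fraction left after cells bearing mature lineage markers were removed (lineage-negative cells). All cultures contained 5% serum and 20 ng/ml stem cell factor. In 3 libraries the cells were untreated and in 3 they had received 1 µg/ml Pam3CSK4, a synthetic triacylated lipopeptide that activates the receptor pair TLR2 and TLR1, with a time of 24 h given for both groups. The libraries held 68559818 to 79064687 counts each over 54057 gene entries, and 21057 entries passed the filter on low counts. Nothing in the labels says that the replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

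The 6 libraries did not lie equally close to one another. Untreated replicates 1 and 2 correlated at Pearson r = 0.993 across the log-CPM of 21057 genes, and Pam3CSK4 replicates 2 and 3 at r = 0.994, although genes are not independent replicates. Untreated replicate 3 correlated with the other untreated libraries at 0.949 and 0.951, and Pam3CSK4 replicate 1 with the other treated libraries at 0.876 and 0.877. In both of these libraries short and GC-rich transcripts were over-represented relative to the other 4. Counts at entries named as pseudogenes made up 8.44% and 11.0% of their totals, against 4.36% to 4.85% elsewhere. The close pairs differed by more than counting noise (chi-square per degree of freedom 5.56 over 20800 genes and 7.20 over 21123 genes). Beyond that noise their counts varied by 4.21% and 4.82% (coefficient of variation), against 45.6% to 77.6% for the other pairs within groups. These values do not tell repeat libraries of 1 sample from separate samples, and the libraries were used as labelled.

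**Figure D1:**
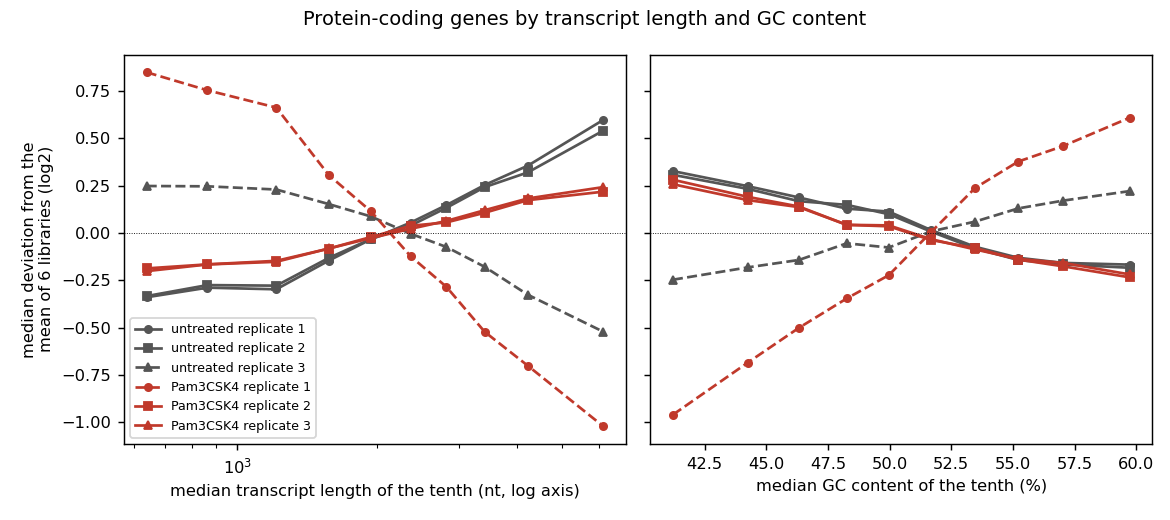
Median deviation of each library from the mean of the 6 libraries (log2 CPM) for 10 equal bins of 8602 protein-coding genes ordered by transcript length (left, nucleotides, log axis) or GC content (right, percent); each point is 1 library in 1 bin, grey for untreated and red for Pam3CSK4, dashed for untreated replicate 3 and Pam3CSK4 replicate 1. In the bin of shortest transcripts these 2 libraries stood at 0.25 and 0.85, and in the longest at -0.52 and -1.02.

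The comparison of treated with untreated cells addresses which transcripts differ in cultures of lineage-negative cells given a TLR2 ligand. The study is concerned with macrophage differentiation and its dependence on C/EBPβ and IRF7. Each library profiles a whole culture, so changes within cells and changes in the mix of cells cannot be told apart here or below. Cytokine, chemokine, interferon-response and phagocyte genes were higher after Pam3CSK4, such as the itaconate enzyme gene Acod1 (259-fold). Mpo, which encodes the myeloperoxidase of primary granules, fell from 5235 ± 346 to 767 ± 286 CPM (SD, n = 3 per group), and Flt3, the receptor tyrosine kinase of early lymphoid and dendritic progenitors, from 56.7 ± 11.0 to 10.9 ± 2.74 CPM. Ccr2, the receptor with which monocytes follow CCL2, fell from 249 ± 49.6 to 14.0 ± 4.89 CPM, whereas Ccl2 itself rose from 0.695 ± 0.140 to 98.1 ± 20.5 CPM. In all, 618 of 21057 genes changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 459 upward and 159 downward, all of them by at least 2-fold. Among genes with a mean log2 CPM above 0, 1900 were at least 2-fold apart between the 4 close libraries. Of these 1900, 1780 moved the same way between the 2 divergent ones (Pearson r = 0.902 across genes). Genes with lower counts were left out of this comparison. Among the 1435 of these 1900 genes that did not pass in all 6 libraries, 1315 moved the same way (r = 0.811). This comparison was chosen after seeing the data. The count itself depended on the libraries: it was 13106 in the 4 close libraries alone, an analysis chosen after seeing the data. With 1 library left out it was 0 without untreated replicate 1, where 1918 of 21707 genes had an unadjusted p under 0.05 by edgeR. It was 0 without untreated replicate 2 (1934 of 21761 genes) and 111 without untreated replicate 3. With no difference at all, a share of 0.05 of the tested genes would be expected under that unadjusted threshold. The count was 1538 without Pam3CSK4 replicate 1, 120 without Pam3CSK4 replicate 2 and 114 without Pam3CSK4 replicate 3. Each gene call named below was lost without untreated replicate 1 and without untreated replicate 2, and DESeq2 called 2140 genes.

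Among the genes of the receptor and pathway that the study names, Tlr2, which binds the lipopeptide, rose from 23.3 ± 1.23 to 80.2 ± 4.34 CPM (SD, n = 3; log2 change 1.78 ± 0.21 SE, adjusted p = 0.0139). It lies on chromosome 3 from 83836272 to 83841767 of GRCm38. Tlr1, its partner for triacylated ligands on chromosome 5 from 64924679 to 64933563, rose from 6.90 ± 0.565 to 77.6 ± 21.7 CPM (log2 change 3.49 ± 0.31, adjusted p = 0.00661). Irf7, the transcription factor that drives type I interferon genes, rose from 4.22 ± 1.14 to 85.5 ± 53.9 CPM (log2 change 4.34 ± 0.56, adjusted p = 0.0183) and lies on chromosome 7 from 141262706 to 141266481. It stood at 147 CPM in Pam3CSK4 replicate 1 and at 49.6 and 59.4 CPM in the other treated libraries. Cebpb, which encodes C/EBPβ on chromosome 2 from 167688915 to 167690418, stood at 22.4 ± 9.77 CPM untreated and 75.6 ± 39.2 CPM treated, a log2 change of 1.76 ± 0.49 that did not pass (adjusted p = 0.159). Its libraries split by replicate as well as by treatment, with log2 differences of 1.66 between the 4 close libraries and 1.84 between the divergent ones (-0.29 and -0.20 for Mtor), on CPM scaled over all 6. Cebpa, encoding C/EBPα, averaged 162 ± 20.6 CPM untreated and 73.7 ± 0.627 CPM treated (adjusted p = 0.0612). The kinase genes Mtor (log2 change -0.28 ± 0.45, adjusted p = 0.811) and Tbk1 (0.40 ± 0.29, adjusted p = 0.615) did not pass. Neither did Tlr6 (1.03 ± 0.37, adjusted p = 0.276), the adaptor gene Myd88 (0.70 ± 0.21, adjusted p = 0.188) or Spi1, which encodes PU.1 (0.60 ± 0.38, adjusted p = 0.565). In the 4 close libraries alone, chosen for their small spread, 13106 of 21514 genes passed, so that passing there says little about a single gene. All 7 genes that did not pass in 6 libraries did so. Cebpb was higher there (adjusted p = 1.00e-11 by edgeR, range 1.00e-11 to 0.616 over the alternatives tried). Mtor was lower (log2 change -0.23 when fitted to these 4, adjusted p = 0.000147, range 0.000147 to 0.999), while without Pam3CSK4 replicate 1 its log2 change was 0.05. Exons of Cebpb overlap those of Tmem189 on the opposite strand over 312 bases. Those of Myd88 overlap Acaa1a over 290 bases and those of Irf7 overlap Phrf1 over 45 bases. Exons of Mpo overlap the antisense entry Gm11505 over 512 bases. Reads could be shared there if counting ignored the strand, and in any case for Rtp4 with Gm45338 (296 bases) and Fpr2 with Fpr3 (48 bases), which overlap on the same strand.

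**Figure D2:**
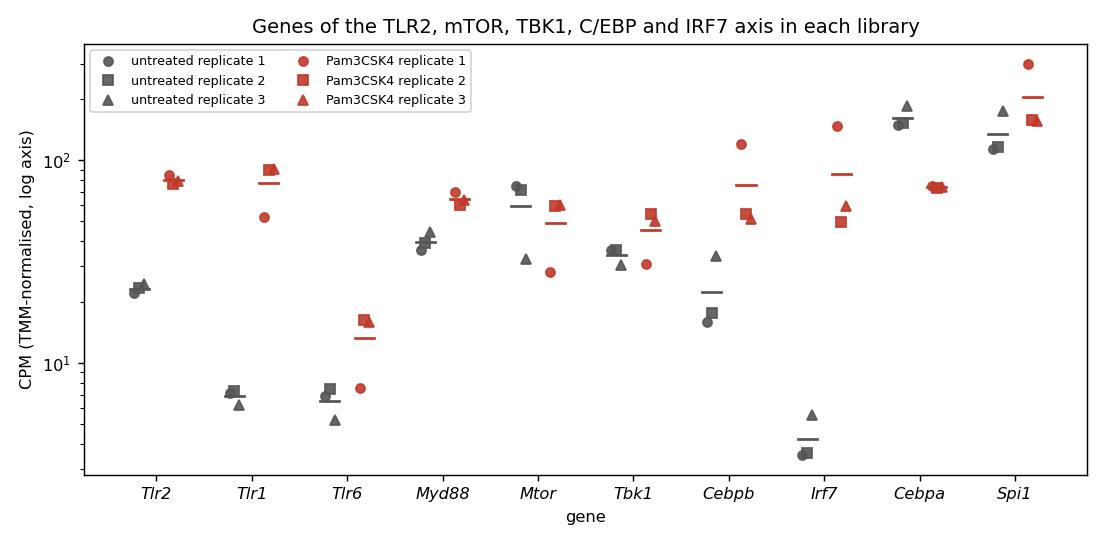
TMM-normalised CPM (log axis) of 10 genes in each of the 6 libraries, grey for untreated and red for Pam3CSK4, with symbols for the replicate and a bar at the mean of each group of 3. The treated values of Tlr2 lie between 76.6 and 85.0 CPM and the untreated ones between 22.1 and 24.5 CPM, while those of Mtor overlap.

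Among the 10 largest rises, Saa3, an acute-phase serum amyloid gene, rose from 1.33 ± 0.969 to 1991 ± 2388 CPM (SD, n = 3; log2 change 10.55 ± 1.58 SE, adjusted p = 0.0311), with 4748 CPM in Pam3CSK4 replicate 1 and 562 and 663 CPM in the other treated libraries. Csf3, which encodes G-CSF, rose from 0.0619 ± 0.0857 to 35.4 ± 14.4 CPM (log2 change 9.11 ± 1.21, adjusted p = 0.0202), and Acod1, whose product makes itaconate, from 2.99 ± 1.31 to 773 ± 87.5 CPM (8.01 ± 0.53, adjusted p = 0.00443). Sprr2d and Lum had no counts in any untreated library, and their treated means were at least 399-fold and at least 136-fold higher, taking 3 counts per library as the floor. In Pam3CSK4 replicate 1 Sprr2d stood at 26.6 CPM and Lum at 1.73 CPM. The other treated libraries had 9.46 and 9.11 CPM for Sprr2d and 6.87 and 6.82 CPM for Lum. Edn1, the endothelin gene, had 2 counts over the untreated libraries and 1305 over the treated ones, a ratio of 718 with an exact 95% Poisson interval of 198 to 5932 that covers counting error only. Ccl7 rose by 8.49 on the log2 scale, Lipg, which encodes endothelial lipase, by 7.98, the dicarboxylate transporter gene Slc13a3 by 7.79 and Lox, which encodes the collagen cross-linking enzyme lysyl oxidase, by 7.78. Untreated replicate 2 had the highest untreated values of Saa3, Csf3, Acod1, Ccl7, Lipg, Slc13a3 and Lox (2.31, 0.160, 4.50, 0.246, 0.111, 1.41 and 1.07 CPM), so that their changes would be larger without it.

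Among the 10 largest falls, Cd209a, a DC-SIGN family lectin gene, averaged 15.0 ± 0.797 CPM in untreated cells and had 2 counts over the 3 treated libraries against 3589 untreated, a ratio of 1632 (exact 95% Poisson interval 451 to 13478, counting error only; adjusted p = 0.00443). Clec10a, a macrophage galactose lectin gene, fell from 190 ± 50.7 to 6.50 ± 0.700 CPM (log2 change -4.87 ± 0.32, adjusted p = 0.00443), and Fn1, the fibronectin gene, from 59.7 ± 28.5 to 2.16 ± 0.525 CPM (-4.78 ± 0.53, adjusted p = 0.0139). The log2 change was -5.61 for Spon2, -4.53 for the entry spelled Retnia, -4.34 for Klrd1, -4.16 for Ccr2, -4.12 for Cd7, -4.11 for Cd300c and -3.87 for Chad, with adjusted p from 0.00443 for Chad to 0.0194 for Klrd1.

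Genes were also grouped into 25 lists fixed in advance, of which 16 moved relative to other genes by limma's camera test with a preset correlation, 12 upward and 4 downward. With a correlation estimated from the data 6 of them held, namely NF-κB response, cytokines and chemokines, interferon-stimulated genes, microbicidal genes, erythroid genes and megakaryocyte genes. In that setting camera also takes its degrees of freedom from the libraries. With the preset correlation it takes them from the number of genes, so those p-values do not reflect the few libraries. The losses are not due to correlation alone. It was estimated at -0.0105 for monocyte and macrophage markers and -0.0496 for p53 targets, under the preset 0.01, yet both lists lost their calls. List members named below that did not pass were chosen for naming after their values were seen.

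**Figure D3:**
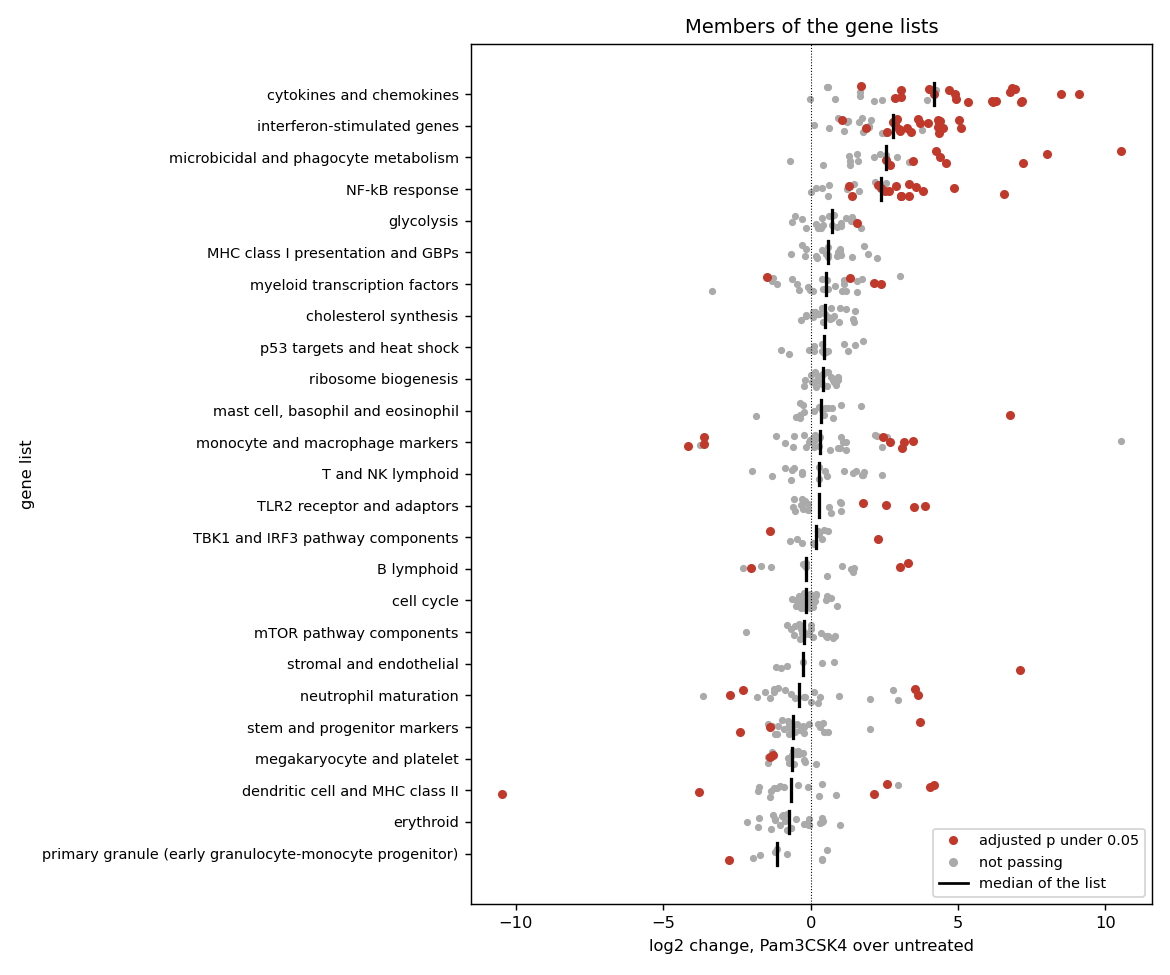
Log2 change (Pam3CSK4 over untreated) of each tested member of 25 gene lists; each point is a gene, red where its adjusted p is under 0.05, and the black bar is the median of the list. Ifng and Lum, with no counts in untreated libraries, are drawn at their lower bounds. Cytokines and chemokines have the highest median, and the primary granule list the lowest, at -1.15.

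Of the 18 tested TLR2 receptor and adaptor genes, 4 rose, none fell and 14 did not pass (6 raised when adjusted over the list alone). The 4 were Cd14 (log2 change 3.89), which presents lipopeptides to TLR2, Tlr1, Irak3 (2.57), an inhibitor of the pathway, and Tlr2. The list moved upward by camera (adjusted p = 0.00625) but not with an estimated correlation (adjusted p = 0.306 with an estimated correlation), nor without untreated replicate 3 (adjusted p = 0.0719), in the 4 close libraries (0.207) or with a term for the 2 divergent libraries (0.0806). Of 25 NF-κB response genes, 15 rose and 10 did not pass (20 raised when adjusted over the list alone), with a median log2 change of 2.39 and a camera adjusted p of 3.08e-20. Ptgs2, which encodes cyclooxygenase 2, rose from 0.386 ± 0.136 to 36.3 ± 29.3 CPM (SD, n = 3; 6.38, 65.0 and 37.5 CPM in the treated libraries; adjusted p = 0.0333 by edgeR), Traf1 by 4.85 on the log2 scale, Nfkbiz by 3.82 and Cd40 by 3.58. Of 31 cytokine and chemokine genes, 20 rose and 11 did not pass (26 raised when adjusted over the list alone), with a median log2 change of 4.25, or 4.19 with Ifng at its lower bound, and a camera adjusted p of 2.42e-33. Besides Csf3 and Ccl7, the neutrophil chemoattractant gene Cxcl2 rose by 7.19 and Ccl2 by 7.14 on the log2 scale.

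Interferon-stimulated genes rose as a group. Of 37 genes, 21 rose and 16 did not pass (34 raised when adjusted over the list alone), with a median log2 change of 2.80 and a camera adjusted p of 1.04e-31. Oasl1 rose from 1.76 ± 0.684 to 60.0 ± 30.5 CPM (SD, n = 3; log2 change 5.09 ± 0.55 SE, adjusted p = 0.0122 by edgeR). Rtp4 rose by 5.03 on the log2 scale, Ifit1 by 4.49 and the ubiquitin-like modifier gene Isg15 by 4.40 (136 CPM in Pam3CSK4 replicate 1 against 36.9 and 43.0 CPM in the others). None of 20 MHC class I presentation and guanylate-binding protein genes passed, over all genes or when adjusted over the list alone. Their median log2 change was 0.60 and the list moved upward (camera adjusted p = 0.0146), though not with an estimated correlation (adjusted p = 0.175 with an estimated correlation) or on total counts alone (adjusted p = 0.0520). The values went from 2.25 for Gbp5 to -0.68 for Tap2. Of 12 TBK1 and IRF3 pathway genes, Ikbke, the kinase gene most related to Tbk1, rose from 42.9 ± 2.52 to 209 ± 50.6 CPM (adjusted p = 0.0156 by edgeR) and Tbkbp1, a TBK1-binding protein gene, fell from 16.5 ± 1.34 to 6.36 ± 0.883 CPM (adjusted p = 0.0408). The other 10 did not pass, the same 2 passed when adjusted over the list alone, and the list did not move (camera adjusted p = 0.762). None of 23 mTOR pathway genes passed, over all genes or when adjusted over the list alone, and the list did not move (camera adjusted p = 0.543, median log2 change -0.21). Among them Deptor, an inhibitory partner of mTOR, stood at 14.4 ± 7.58 CPM untreated and 3.11 ± 2.07 CPM treated (adjusted p = 0.280 by edgeR), and Rptor at 39.1 ± 7.84 and 34.5 ± 4.24 CPM.

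Genes of the monocyte, macrophage and dendritic lineages went both ways. Of 36 monocyte and macrophage markers, 5 rose, 3 fell and 28 did not pass (11 raised and 4 lowered when adjusted over the list alone). The lectin genes Clec4n (log2 change 3.48) and Clec4e (3.16), Adgre1 (3.11), which encodes F4/80, the scavenger receptor gene Msr1 (2.69) and the Fc receptor gene Fcgr1 (2.45) rose. Ccr2 (-4.16) and the efferocytosis receptor gene Axl (-3.62) were among those that fell. Marco, a scavenger receptor gene, averaged 2.70 ± 4.09 CPM untreated and 3997 ± 3145 CPM treated (SD, n = 3) and did not pass (adjusted p = 0.0556 by edgeR), with 7.42 CPM in untreated replicate 2 against 0.286 and 0.402 CPM in the other untreated libraries. Before TMM scaling, which widens this gap, Marco stood at 4384 CPM in Pam3CSK4 replicate 1 and averaged 2476 CPM in Pam3CSK4 replicates 2 and 3. Csf1r, the receptor gene for M-CSF, stood at 347 ± 24.6 and 229 ± 12.1 CPM (adjusted p = 0.369). The list moved upward (camera adjusted p = 0.0143), though not with an estimated correlation (adjusted p = 0.120 with an estimated correlation) or with offsets for length and GC content (0.0614). Of 20 dendritic cell and MHC class II genes, 4 rose, 2 fell and 14 did not pass (5 raised and 7 lowered when adjusted over the list alone). The migration receptor gene Ccr7 (log2 change 4.19), the costimulatory genes Cd80 (4.04) and Cd86 (2.14), and Cd83 (2.58) rose, while Cd209a (-10.47) and Siglech (-3.77), a plasmacytoid dendritic cell marker, fell. The list as a whole did not move (camera adjusted p = 0.417). Of 21 microbicidal and phagocyte metabolism genes, 9 rose and 12 did not pass (18 raised and 1 lowered when adjusted over the list alone), with a median log2 change of 2.57 and a camera adjusted p of 2.04e-19. Besides Saa3 and Acod1, Socs1, a cytokine signalling inhibitor gene, rose by 4.59 on the log2 scale. Nos2, the inducible nitric oxide synthase gene, rose to 1.01 to 3.63 CPM from 4 counts, all in untreated replicate 2, so that the size of its change is uncertain.

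Of 9 primary granule genes, Mpo fell (log2 change -2.77 ± 0.46 SE, adjusted p = 0.0387 by edgeR) and 8 did not pass, with the same 1 lowered when adjusted over the list alone. Elane, encoding neutrophil elastase, stood at 558 ± 212 CPM untreated and 145 ± 104 CPM treated (SD, n = 3; adjusted p = 0.209 by edgeR). The list moved downward (camera adjusted p = 0.0179, median log2 change -1.15), though not with an estimated correlation (adjusted p = 0.385 with an estimated correlation), nor without untreated replicate 3 (adjusted p = 0.0974), Pam3CSK4 replicate 2 (0.0752) or Pam3CSK4 replicate 3 (0.0882). Of 24 neutrophil maturation genes, the formyl peptide receptor genes Fpr1 (3.65) and Fpr2 (3.53) rose, the secondary granule gene Ltf (-2.75) and Itgb2l (-2.29) fell, and 20 did not pass (4 raised and 8 lowered when adjusted over the list alone). That list did not move (camera adjusted p = 0.197), except without Pam3CSK4 replicate 1 (adjusted p = 0.0345). Of 28 myeloid transcription factor genes, Atf3 (2.38), Maff (2.15) and Junb (1.32) rose, Gfi1 (-1.47), a repressor needed for granulocyte formation, fell, and 24 did not pass (8 raised and 4 lowered when adjusted over the list alone). Irf8 stood at 163 ± 1.72 CPM untreated and 65.7 ± 12.4 CPM treated (adjusted p = 0.0516 by edgeR). The list moved upward (camera adjusted p = 0.0320), though not with an estimated correlation (adjusted p = 0.214 with an estimated correlation), with the stricter filter (0.348), or without untreated replicate 3 (0.0721), Pam3CSK4 replicate 2 (0.0791) or Pam3CSK4 replicate 3 (0.0882).

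Among genes of stem cells and early progenitors, Flt3 (log2 change -2.38) and Tie1 (-1.39) fell and Procr (3.72), which encodes the endothelial protein C receptor, rose, while 26 of 29 did not pass (2 raised and 4 lowered when adjusted over the list alone). Kit stood at 143 ± 63.4 CPM untreated and 64.1 ± 42.4 CPM treated, Cd34 at 227 ± 1.53 and 97.7 ± 5.18 CPM (SD, n = 3; adjusted p = 0.569 and 0.0522 by edgeR). The list moved downward (camera adjusted p = 0.0291), though not with an estimated correlation (adjusted p = 0.365 with an estimated correlation), on total counts alone (0.145) or without Pam3CSK4 replicate 1 (0.0903). None of 26 erythroid genes passed, over all genes or when adjusted over the list alone, but the list moved downward (camera adjusted p = 0.000274, median log2 change -0.73). Its median was -0.84 between the 4 close libraries and -0.49 between the divergent ones, with the same direction in both for 17 of the 26 genes. The globin gene Hba-a1, which may share reads with its near-identical copy Hba-a2, had log2 differences of -0.56 and 0.86 in these 2 sets. Of 19 megakaryocyte and platelet genes, F2rl2 (-1.37), a thrombin receptor gene, and the collagen receptor gene Gp6 (-1.26) fell and 17 did not pass (5 lowered when adjusted over the list alone), and the list moved downward (camera adjusted p = 5.78e-05).

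Of 18 mast cell, basophil and eosinophil genes, Il13 rose from 0.0370 ± 0.0326 to 4.22 ± 0.497 CPM (SD, n = 3; adjusted p = 0.0194 by edgeR) and 17 did not pass (1 raised and 1 lowered when adjusted over the list alone; camera adjusted p = 0.298). Of 15 B lymphoid genes, Blnk (log2 change 3.31) and Pou2af1 (3.03) rose, Dntt (-2.01), the terminal transferase gene of early lymphoid cells, fell, and 12 did not pass (3 raised and 2 lowered when adjusted over the list alone). Blnk is an adaptor gene also used in macrophages. For this list the median log2 change (-0.14) was negative, the mean (0.28) and the camera direction were positive, and the list did not move (camera adjusted p = 0.300) except upward with the stricter filter (adjusted p = 0.00219). None of 19 T and NK lymphoid genes passed (5 raised and 1 lowered when adjusted over the list alone; camera adjusted p = 0.134), although the list moved upward with no filter (adjusted p = 0.0443) and without Pam3CSK4 replicate 2 (0.0490). Of 7 tested stromal and endothelial genes, Lum rose and 6 did not pass, as when adjusted over the list alone. The median of this list was -0.26, its mean 1.36 (0.72 with Lum at its lower bound) and its camera direction positive (adjusted p = 0.643).

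Of 21 glycolysis genes, Slc2a1, the glucose transporter gene GLUT1, rose from 25.2 ± 1.74 to 75.8 ± 2.52 CPM (SD, n = 3; adjusted p = 0.0174 by edgeR) and 20 did not pass, with the same 1 raised over the list alone. Eno1 stood at 235 ± 90.5 CPM untreated and 762 ± 675 CPM treated (adjusted p = 0.349). The list moved upward (camera adjusted p = 0.00252, median log2 change 0.74), though not with an estimated correlation (adjusted p = 0.178 with an estimated correlation). None of 23 cholesterol synthesis genes and none of 21 ribosome biogenesis genes passed, over all genes or when adjusted over the list alone. Both lists moved upward (camera adjusted p = 0.00309 and 0.00635), with medians of 0.49 and 0.42, though not with an estimated correlation (adjusted p = 0.175 and 0.165 with an estimated correlation). In the cholesterol list Idi1 stood at 68.4 ± 3.13 CPM untreated and 137 ± 35.7 CPM treated, and among ribosome biogenesis genes Ncl, the nucleolin gene, at 847 ± 71.9 and 1248 ± 304 CPM. None of 15 p53 target and heat shock genes passed (2 raised when adjusted over the list alone), among them Cdkn1a at 50.7 ± 6.56 and 122 ± 31.7 CPM (adjusted p = 0.0812 by edgeR). That list moved upward (camera adjusted p = 0.0431, median log2 change 0.45), though not with an estimated correlation (adjusted p = 0.178 with an estimated correlation), on total counts alone (0.0933) or with the stricter filter (0.0501), nor without untreated replicate 1 (0.0600), 2 (0.0825) or 3 (0.0666), or Pam3CSK4 replicate 2 (0.0791) or 3 (0.101). None of 35 cell cycle genes passed, over all genes or when adjusted over the list alone, and the list did not move (camera adjusted p = 0.489, median log2 change -0.16), with Mki67 at 312 ± 114 CPM untreated and 265 ± 51.4 CPM treated.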

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

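The 4 close libraries, the term for the 2 divergent libraries, the length covariate and both analyses of protein-coding genes were chosen after the data were seen. The cause was not tested unless stated. Of 618 changed genes (459 raised, 159 lowered, 618 by at least 2-fold), none changed sign in any alternative. Each alternative used some or all of the same libraries, so this and the numbers kept below are no independent checks. Fewer genes passed on total counts alone (333, with 237 raised and 96 lowered, 333 by 2-fold), which kept 273 of the 618 and ended the calls of 22 of 64 named genes. There the median log2 change of all genes was -0.24 against -0.02 with TMM. The stricter filter tested 12839 genes and gave 399 (284 raised, 399 by 2-fold), keeping 374 of the 377 present. Without a filter 93 were lowered. More passed with DESeq2 (2140, with 1382 raised and 758 lowered, 1911 by 2-fold), which was run on 32427 entries without the filter, so that tool and filter both differ, and limma-voom lowered 249. In the 4 close libraries alone 13106 genes passed (6719 raised, 6387 lowered, 3425 by 2-fold), among them 617 of the 618. The term for the 2 divergent libraries gave 5398 (2531 raised, 2867 lowered, 2797 by 2-fold) and the length covariate 6377 (3113 raised, 3264 lowered, 2615 by 2-fold), each with all 618. Protein-coding genes alone gave 284 lowered, and with offsets for length and GC content 1679 changed (848 raised, 831 lowered, 1276 by 2-fold), keeping 492 of the 508 present.

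With 1 library left out the number changed ranged from 0 to 1538, raised from 0 to 1032, lowered from 0 to 506 and changed by 2-fold from 0 to 1444. The number changed was highest without Pam3CSK4 replicate 1 and 0 without untreated replicate 1 or 2. Without these untreated libraries edgeR left 1918 of 21707 and 1934 of 21761 genes at an unadjusted p under 0.05. All 64 named genes that had passed lost their call without either of these untreated libraries, 41 without untreated replicate 3, 42 without Pam3CSK4 replicate 2, 42 without replicate 3 and 0 without replicate 1. Deviations from the group means of equally numbered libraries correlated across genes at -0.71, 0.64 and -0.76, and not every library correlated best with its own number. The signs follow from which library diverges in each group. They therefore cannot tell whether a replicate number marks a shared animal, culture or day. With the number as a replicate block 0 genes changed by edgeR (0 raised, 0 lowered, 0 by 2-fold), with 1568 of 21057 at an unadjusted p under 0.05. With that block the call of the p53 and heat shock list ended (camera adjusted p = 0.0544).

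Of the 16 lists that moved, 6 held with an estimated correlation, 13 on total counts, 14 with the stricter filter and 15 in the 4 close libraries. Over all alternatives the adjusted p ranged from 0.000620 to 0.306 for the TLR2 list, 0.00468 to 0.175 for MHC class I, 0.00552 to 0.120 for monocytes and macrophages. It ranged from 0.000599 to 0.385 for primary granules, 0.00292 to 0.348 for myeloid transcription factors and 0.00364 to 0.365 for stem and progenitor markers. The range was 0.000149 to 0.165 for ribosome biogenesis, 0.000246 to 0.178 for glycolysis, 5.29e-06 to 0.175 for cholesterol synthesis and 0.00354 to 0.178 for p53 targets. Results that did not pass and turned direction were Mtor (log2 change 0.0884 with the length covariate, and with 1 library left out from -0.505 without untreated replicate 3 to 0.0527 without Pam3CSK4 replicate 1) and 2 lists. These are the stromal list (adjusted p = 0.599 without a filter, 0.687 with the stricter one, 0.632 in the 4 close libraries, and with 1 library left out 0.458 to 0.982, with 0.800 without Pam3CSK4 replicate 2 and 0.663 without replicate 3) and the TBK1 list (0.292 to 0.986 with 1 library left out). In simulated counts with the spread of all 6 libraries, the test recovered 0% of changes of 1 on the log2 scale and 20% of changes of 3. That simulation drew independent noise, so it does not measure how often the real comparison misses a change. Genes that did not pass may include changes of either size and larger ones, as for Marco above.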

Other observations

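The tests by gene family and the genes named from them, and all tests below except that of other splits of the libraries, were chosen after the results were seen. Among 258 families of at least 8 tested genes that share the letters of their symbol, genes whose symbols have the letters Il before the first digit, which include interleukins and their receptors, had a higher share of raised genes than the other tested genes (13 of 59 raised, one-sided Fisher's exact test, adjusted p = 4.44e-08). Apart from Il10, Il13, Il1b, Il1rn and Il6, which belong to lists above, they included Il5, the eosinophil growth factor gene, which rose from 0.0971 to 4.79 CPM, and Il22, without counts in untreated libraries and at least 11.0-fold higher in treated ones. Il2ra, which encodes the high-affinity chain of the IL-2 receptor, rose from 1.86 to 14.4 CPM, and Il1f9, which encodes IL-36γ, from 14.6 to 112 CPM. The edgeR adjusted p was 0.00637 for Il5, 0.0390 for Il22, 0.0156 for Il2ra and 0.0342 for Il1f9, and in each case all 3 treated libraries lay above all 3 untreated ones. The tumor necrosis factor receptor family also had a higher share (4 of 18 raised, adjusted p = 0.0173 by Fisher's exact test), such as Tnfrsf9, which encodes 4-1BB and went from 0.492 to 8.95 CPM.

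Serine protease inhibitors of the Serpina family (7 of 12 raised, adjusted p = 1.38e-07 by one-sided Fisher's exact test) and survival genes of the Bcl2a1 group within the Bcl family (5 of 23 raised, of which 4 are Bcl2a1 copies and 1 is Bcl3, adjusted p = 0.00504) include similar copies that may share reads, which was not tested, so their members may not be separate events. Serpina3g stood at 46.8 CPM untreated and 454 CPM treated, and Bcl2a1d at 2.77 and 377 CPM. Before TMM scaling, which widens this gap, Bcl2a1d stood at 406 CPM in Pam3CSK4 replicate 1 and averaged 240 CPM in Pam3CSK4 replicates 2 and 3. Genes whose symbols have only the letters Cd before the first digit held 11 raised and 9 lowered of 91 (adjusted p = 0.000238 and 7.58e-06 by one-sided Fisher's exact test). Similar Cd209 copies are among the lowered genes and may share reads, which was not tested, so they may not be separate events. The DC-SIGN family copies Cd209b, Cd209d and Cd209e had no counts in treated libraries and were at least 3.88-fold, 23.7-fold and 6.20-fold lower there. Cd38, an NAD-consuming ectoenzyme gene, rose from 1.37 to 47.2 CPM. Matrix metalloproteinases did not pass as a family (3 of 16 raised, adjusted p = 0.109), with Mmp14 at 19.1 and 405 CPM and Mmp2 at 2.16 and 44.2 CPM.

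Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 618 genes, the real one, and the highest other number was 0. Every other split mixes treated and untreated libraries within a group, so any treatment difference adds to its spread and lowers its number. The contrast with the real split is therefore no separate support. These 10 splits are also too few for a share under 0.05.

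Untreated replicate 3 and Pam3CSK4 replicate 1 deviated from the other libraries of their groups in the same direction, with deviations that correlated at r = 0.901 across 8602 genes. Exchanged or wrong group labels are argued against, since on 1103 genes that separate the 4 close libraries the median position from untreated (0) to treated (1) was 0.0669 for untreated replicate 3 and 0.996 for Pam3CSK4 replicate 1. Transcript length and GC content explained 40.0% of the variance of the deviation of Pam3CSK4 replicate 1 and 45.7% of that of untreated replicate 3, against 4.77% and 3.50% of the differences within the close pairs. This is consistent with a bias of library preparation or RNA quality that favours short, GC-rich transcripts in these 2 libraries, as a hypothesis that leaves part of the variance open. No biological explanation was tested, because the labels name no factor that these libraries share.

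Untreated replicate 2 held low levels of transcripts that are abundant in treated cells, such as Marco (7.42 CPM against 0.286 CPM in untreated replicate 1). Its excess over untreated replicate 1 was taken for 21 genes with a mean of at least 20 CPM in Pam3CSK4 replicates 2 and 3. That mean was at least 50-fold above untreated replicate 1. The excess was positive for all 21, against 11 in untreated replicate 3. Choosing genes that were low in untreated replicate 1 favours a positive excess in either library. Untreated replicate 3 also has a length and GC trend of its own. In untreated replicate 2 the excess amounted to a common share of 0.338% ± 0.0116 (SE) of the level in Pam3CSK4 replicates 2 and 3, with an interquartile range of 0.240% to 0.522%. The shares varied by more than counting noise (chi-square 46.4 on 20 degrees of freedom), and with Pam3CSK4 replicate 1 as the source the chi-square was 5.07 times as large, which does not decide between sources because that library has a length and GC trend of its own. A small admixture of treated material or of its reads may account for the excess, while a weak response of the untreated culture itself was not tested and stays open.

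Immunoglobulin transcripts were higher in treated libraries, with 19 of 105 kappa and 4 of 94 heavy chain variable segments raised in all 6 libraries (adjusted p = 3.14e-10 and 1.00 by one-sided Fisher's exact test), 87 and 91 segments raised in the 4 close libraries, and of 9 constant genes Ighg2c passing in all 6 (adjusted p = 0.0396 by edgeR). Variable segments include similar copies that may share reads, which was not tested, so they may not be separate events as Fisher's test assumes. Of all genes tested in the 4 close libraries, 6719 of 21514 were raised. Igkc stood at 885 CPM untreated and 3760 CPM treated and Igha at 88.1 and 1520 CPM (adjusted p = 0.289 and 0.0528 by edgeR, so neither passed). In Pam3CSK4 replicate 1 they stood at 7666 and 3017 CPM. The other treated libraries had 1817 and 1799 CPM for Igkc and 749 and 796 CPM for Igha. The length and GC trend of Pam3CSK4 replicate 1 is argued against as the whole cause, since between the 4 close libraries, which leave it out, the 9 constant genes were all higher, by a median log2 change of 1.91 (2.50 between the divergent libraries). A larger share of plasma cells may contribute, although lineage depletion is meant to remove mature cells: 13 other plasma cell markers, of which Irf4 and Cd79a also stand in other lists, had a median log2 change of 0.976 between the 4 close libraries (quartiles 0.22 and 1.51), with 11 of 13 higher. The markers moved apart, with Jchain at 60.1 and 186 CPM, Xbp1 at 164 and 164 CPM and the surface marker gene Sdc1 at 23.8 and 11.0 CPM, so they do not decide whether plasma cells were more frequent or transcription in B-lineage cells differed.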
